A study of Mus musculus with 4 samples.

How the data were processed

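The series holds 4 single-cell libraries of healthy adult mouse prostate, each from 1 mouse, with the anterior, ventral and dorsolateral lobes combined. Per the labels, tissue for 3 libraries was digested for 1 h with cold protease at 10 mg/mL, and tissue for 1 library for 1 h with collagenase I at 1.5 mg/mL. The digestion temperature is not given. A CD326-negative fraction was taken magnetically from 1 of the cold protease suspensions, and the other suspensions were not sorted. The groups are therefore cold protease unsorted (n = 2), cold protease CD326-negative (n = 1) and collagenase unsorted (n = 1). Per the labels, about 17400 cells were loaded per library with 10x Genomics 3′ kits of versions v2 and v3. The labels do not say which library had which kit.

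The deposited files hold raw UMI counts per gene and barcode, made by the submitters with Cell Ranger 3.1.0 against mm10, per the submitters' processing notes. Reads from a NextSeq and a NovaSeq instrument were combined before counting, per the labels. The gene annotation, and the treatment of reads shared by near-identical genes, are not given. The matrices list 31053 genes and 61014 barcodes that Cell Ranger had called as cells. Of the gene identifiers, 31011 were found in the GENCODE vM21 annotation of GRCm38, the assembly of mm10, which supplied the positions printed. Cell annotations of the submitters were not used here.

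Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept. Scrublet, run per library through scanpy 1.11.5, called 73 doublets in cold protease library 1, 0 in cold protease library 2, 1 in the CD326-negative library and 3 in the collagenase library. A caller that marks so few of so many cells has not worked, so doublets largely remain in the data. The filters left 5086, 23207, 13727 and 5027 cells in the same order. The 4 libraries were clustered jointly (Python 3.11.15, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3) on 2000 variable genes, with all members of the fixed gene lists left out, 40 principal components, 15 neighbours, Leiden resolution 1 and seed 1. No batch correction was applied. This gave 46 clusters.

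Clusters were named "X-like" from marker lists fixed before the data were examined, and 11 classes resulted. A name needed at least 3 markers, each detected in 10% of the cells and at 20% or more of its highest cluster. Only markers at 100 CPM or more in some cluster of the library were counted. It also needed a marker among the 10 leading genes with a marker score of 0.4, or a score of 0.5 without a leading marker. Clusters with markers of a second type and a median doublet score of 0.15, or with a score of 0.25 alone, stayed unnamed. The same held for shallow clusters without a leading marker and for clusters with more leading markers of another type. These naming thresholds were set after the clusters were seen, and they left 8.49% of kept cells unnamed in cold protease library 1, 7.15% in cold protease library 2, 4.92% in the CD326-negative library and 1.17% in the collagenase library. In the collagenase library Hbb-bs was detected at a similar share in every cluster and was not counted against a name. Class shares have exact binomial (Clopper-Pearson) intervals at 95%, and CPM values have exact Poisson intervals; both cover counting error only. A count of 0 was given the limit of 3 counts of the total.

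CPM values, scaled to the UMI total of the library and class, were computed from the deposited counts summed per library and class. Genes were tested on those sums with edgeR 4.0.16 (R 4.3.3): TMM normalisation, filterByExpr, estimateDisp, glmQLFit with its legacy default, glmQLFTest, and Benjamini-Hochberg adjustment at 0.05. The enzyme contrast (collagenase unsorted minus cold protease unsorted) and the sort contrast (CD326-negative minus cold protease unsorted) were fitted on group alone. The enzyme contrast was planned for lobar luminal-like, basal-like, fibroblast-like and smooth muscle-like cells and the sort contrast for the latter pair, each with at least 20 cells in every library; other classes were not tested for genes between groups. They have 1 residual degree of freedom, which comes from the cold protease unsorted libraries, and the lone library is assumed to vary like them. Contrasts between classes had library as a block, with 3 residual degrees of freedom. Their p-values refer to classes found in the same cells, so they describe those classes and are too small as evidence that separate classes exist. The class shares are given as values and were not tested. Standard errors are the log2 fold change divided by the square root of the quasi-likelihood F, and are approximate.

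The 18 gene lists fixed before the data were examined were immediate early, heat shock, cold-inducible, NF-kB and chemokine, androgen response, progenitor-associated, secretory pathway, mucosal defence, Wnt, BMP and TGF-beta, growth factor, complement, matrix, contractile, adventitial fibroblast, steroid hormone, cell cycle and RNA quality. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and at an estimated one, and with fry, adjusted over 159 tests of list and contrast. Some genes belong to more than 1 list. In the enzyme and sort contrasts, the genes named are the 12 with the largest log2 fold change each way among those that passed, had at least 50 CPM in the higher group and lay beyond both cold protease unsorted libraries, leaving out mitochondrial, ribosomal, Gm and Rik names and markers of other classes. Where fewer than 5 passed in a direction, up to 10 genes at least 2-fold beyond each of the unsorted libraries are given by size alone. In class contrasts they are the 12 list members that passed with the largest change each way and the same direction in every library, and the 5 largest other genes each way that were not clustering features. Beyond these, members of a list were named by the size of their change. Some genes that meet these rules are not printed. Fibroblast-like cells were clustered again at resolution 0.5 after centring each gene within its library, a step chosen after clusters were seen to follow libraries, and each subcluster with at least 20 cells on both sides in at least 2 libraries was tested against the other fibroblast-like cells.

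Simulated counts were drawn from a single mean profile over the sums of a contrast, the libraries' totals and the trended dispersion. Baseline differences between libraries or classes were thus left out. The test was tried on these counts with 200 changed genes. Of genes changed 8-fold it recovered 86.3% in the enzyme contrast of lobar luminal-like cells (14287 genes), 44.8% in basal-like cells (12626 genes), 11.1% in fibroblast-like cells (11583 genes) and 3.88% in smooth muscle-like cells (3896 genes). In the sort contrast of fibroblast-like cells it recovered 6.32% (11584 genes). In class contrasts it recovered 98.1% for proximal against lobar (11968 genes), 98.9% for basal against lobar (12698 genes) and 100% for fibroblast against muscle (5638 genes). Of genes changed 2-fold it recovered 7.92%, 1.11%, 0%, 0%, 0%, 56%, 30.2% and 25.3% in the same order. The sort contrast of smooth muscle-like cells (3852 genes), added to the simulation later, recovered 0.885% and 0%. False calls made up 5.26%, 4%, 7.69% and 20% of the calls in the enzyme contrasts in the order above. They made up 0% in both sort contrasts and 6.06%, 3.85% and 2.8% in the class contrasts.

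Alternatives fixed before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no low-count filter, doublets kept, cells with at least 1000 genes and at most 5% mitochondrial UMIs, cells with at least 200 genes and at most 25%, resolution 2, each library clustered alone, secretory marker genes left out, each library left out, all cold protease libraries as the reference, no library block, cells thinned to 1000 UMIs, camera with an estimated correlation and subclustering at resolution 1. Chosen after seeing the data were a reference of cold protease library 1 with the CD326-negative library, removal of the highest doublet scores at 0.8% per 1000 barcodes, edgeR without its legacy option, and the macrophage-like share without cluster 37 or with unnamed cluster 18.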

Results

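Prostate tissue of healthy adult mice was dissociated in different ways and its single cells were profiled by droplet RNA sequencing. The epithelium of this gland consists of secretory luminal cells in the lobes, a luminal type near the urethra, and basal cells beneath them, all of which carry Epcam (CD326) on their surface. Cold protease library 1 had 7139 barcodes and 37979769 UMIs, and cold protease library 2 had 27432 barcodes and 124397404 UMIs. The CD326-negative library had 17471 barcodes and 121968732 UMIs, and the collagenase library had 8972 barcodes and 65846194 UMIs. Cold protease library 2, and by a small margin the CD326-negative library, thus had more barcodes than the 17400 cells loaded. Kept cells had a median of 4784.5, 4738, 4295 and 5373 UMIs and of 1466, 1366, 1570 and 1783 genes in that order. Each library came from 1 mouse, and the groups of 1 library have no replicate.

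Epcam, the target of the magnetic depletion (ENSMUSG00000045394, chromosome 17, 87635979 to 87651129, mm10), was measured in every library. In lobar luminal-like cells it stood at 296.5 CPM (95% Poisson interval 290 to 304) in cold protease library 1, 272 CPM (268 to 275) in library 2, 313 CPM (309 to 317) in the CD326-negative library and 682 CPM (672 to 691) in the collagenase library. In basal-like cells it stood at 166, 114, 198 and 659 CPM in the same order, and in proximal luminal-like cells at 803, 408, 964 and 1902 CPM. Averaged over the class, the lobar and proximal luminal-like cells left in the CD326-negative library thus had no less Epcam RNA than those of either unsorted cold protease library. For basal-like cells this is not clear, because their Epcam was near that of cells that should lack it: in library 2 fibroblast-like, macrophage-like and endothelial-like cells had 191, 194 and 230 CPM, and in the CD326-negative library T/NK-like cells had 191 CPM. In the CD326-negative library, with each cell thinned to 1000 UMIs, 29.9% of lobar luminal-like, 17.9% of basal-like and 61.1% of proximal luminal-like cells had an Epcam UMI, against 4% of fibroblast-like and 12.1% of T/NK-like cells, which should lack it. Without thinning these shares were 90.2%, 46.9%, 97.9%, 14.8% and 38.8%, at median depths of 14707, 3586, 8058, 2707 and 2474 UMIs.

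The sort comparison asked what depletion of CD326-positive cells did to the make-up of a cold protease suspension. Epithelial cells still made up 74.9% of the kept cells (95% binomial interval 74.2 to 75.6) after depletion, beside 76.8% and 86.6% in the unsorted libraries. This share depends on the naming rule, since unnamed clusters were left out of it. Cluster 15, led by Svs2 and Pate4, was 0.634% after depletion, beside 4.19% and 2.36%. Cluster 17, led by basal genes, was 0.0219%, beside 0.0393% and 3.14%, and cluster 35, led by Spink5, was 1.46%, beside 0.0197% and 0.00862%. Within the epithelium the balance was different. Lobar luminal-like cells, named from Pbsn, Msmb and other secretory markers, were 32.4% after depletion and 49.7% and 67.7% without it, a ratio of 0.551 to the unsorted mean. Basal-like cells, named from Krt5, Krt14, Krt15 and Trp63, were 40.4% against 24.97% and 13.1%, a ratio of 2.12. The lobar and basal-like values lay beyond both unsorted libraries. The lobar class also differed in make-up (a leading gene of each cluster in brackets), so its ratio does not describe every cluster. After depletion cluster 5 (Sbp) was 45.95% of the class and cluster 11 (Msmb) 21.7%, against 16.8% and 3.68% in library 1. Cluster 7 (Ren1) was 15.1% and cluster 9 (Nlrp10) 14.0%, against 48.5% and 28.3%. In library 2, cluster 0 (Ren1) was 48.0%, cluster 2 (Nlrp10) 20.6%, cluster 3 (Sbp) 20.4% and cluster 16 (Msmb) 4.87%. Proximal luminal-like cells (Krt4, Psca) were 2.12% and lay between the unsorted values of 2.03% and 3.92%. Fibroblast-like cells (Dcn, Lum, Pdgfra) were 7.70% against 5.05% and 2.30%, and macrophage-like cells (C1qa, Csf1r) were 8.46% against 4.74% and 2.76%. T/NK-like cells were 0.488% (0.378 to 0.619) against 1.47% in library 1 and 0.534% (0.445 to 0.637) in library 2. They were thus lower than in library 1 and level with library 2 within counting error. The unsorted libraries differ widely from each other, and shares are given as values without a test.

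The comparison between enzymes carries a limit that applies to the shares and to the genes of every class. The collagenase library shared 1, 12 and 5 barcodes with cold protease libraries 1 and 2 and the CD326-negative library, where the rate among cold protease pairs would give 90.3, 347 and 221. The 10x barcode list, and with it the kit, therefore differs together with the enzyme and with any difference between mice, and these cannot be told apart.

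The class shares of the collagenase library were set beside those of the unsorted cold protease libraries. The collagenase library held higher shares of fibroblast-like, macrophage-like and T/NK-like cells. Fibroblast-like cells were 16.9% of its kept cells (15.8 to 17.9), which is 4.59 times the cold protease mean, 3.34 times library 1 and 7.33 times library 2, and 8.31 times the mean with the stricter cell filter. Macrophage-like cells were 8.73%, a ratio of 2.33, and 33.9% of them formed cluster 37, led by Lyz1 and Retnla. Without that cluster the ratio was 1.54, and it was 1.71 when unnamed cluster 18, also led by Lyz1 and Retnla, was counted with the class; both were calculated after the clusters were seen. T/NK-like cells (Cd3g, Nkg7, Trbc2) were 2.57% against 1.47% and 0.534%, a ratio of 2.55, or 9.51 with the stricter cell filter. Basal-like cells were 9.69%, a ratio of 0.509, and proximal luminal-like cells were 0.497%, a ratio of 0.167. The shares of these 5 classes lay beyond both unsorted cold protease libraries. Lobar luminal-like cells, at 58.3%, and smooth muscle-like cells (Acta2, Myh11, Actg2), at 0.477%, lay between them, and the lobar ratio of 0.993 was 0.584 with the stricter cell filter. Seminal vesicle-like cells, led by Svs genes, were 1.84% of cold protease library 2 and 0.0786% of library 1, and 0 of 5027 cells of the collagenase library, which allows up to 0.0597%. Smaller classes were blood endothelial-like cells (Pecam1, Cdh5), at 1.06%, 0.366%, 1.89% and 0.895% in cold protease libraries 1 and 2, the CD326-negative and the collagenase library, lymphatic-like cells (Prox1, Lyve1) at 0.177%, 0.0905%, 0.102% and 0.358%, and B-like cells (Cd79a, Ms4a1) at 1.63%, 0.0948%, 0.619% and 0.438%. The T/NK ratio was 4.80 against library 2 alone and 1.74 against library 1 alone.

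**Figure D1:**
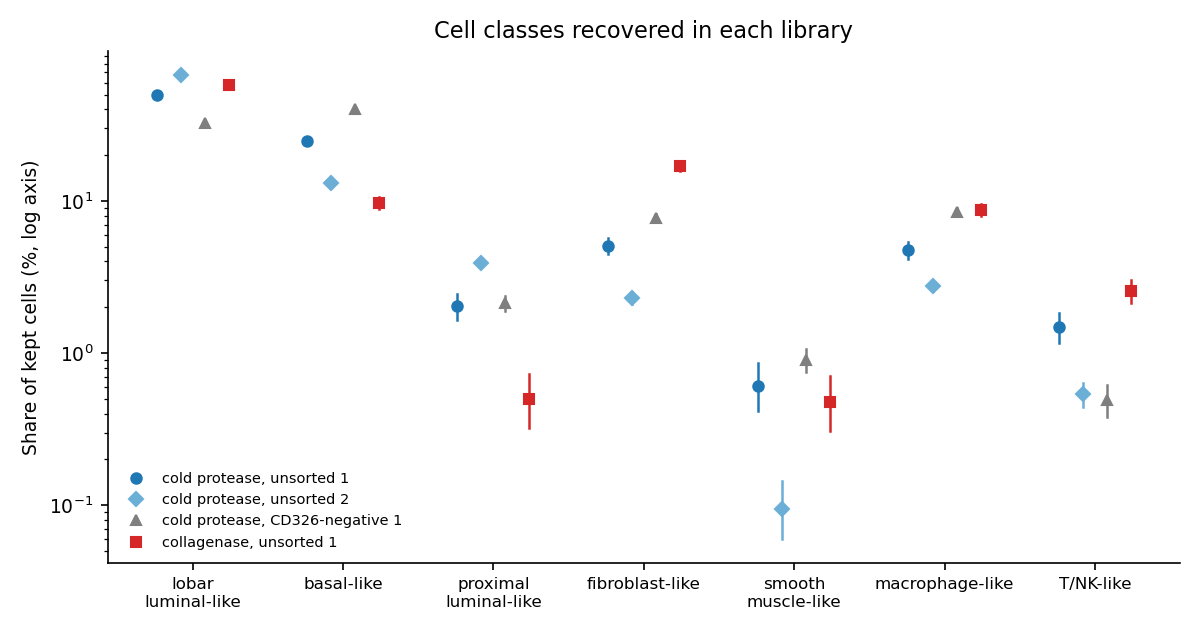
Share of kept cells in % (log axis) of 7 classes in each of the 4 libraries, with 95% binomial intervals as vertical lines. The collagenase library holds the highest share of fibroblast-like cells, at 16.9%, and the lowest of proximal luminal-like cells, at 0.497%.

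Lobar luminal-like cells of the collagenase library carried a strong immediate early response. These genes encode short-lived transcription factors and feedback regulators that a cell switches on within minutes of a stimulus. Fosb, an AP-1 subunit (ENSMUSG00000003545, chromosome 7, 19302696 to 19310051, mm10), rose most: 452 CPM in the collagenase library and 0.214 and 0.353 CPM in cold protease libraries 1 and 2. Its log2 fold change was 10.25 (SE 0.45, adjusted p = 2.27e-10 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Fos rose by 7.54 (SE 0.42), from 4.11 and 3.85 CPM to 895 CPM, and Atf3, a stress-induced repressor, by 6.82 (SE 0.44). Egr1 rose by 6.64, Jun by 5.85, Btg2 by 4.67 and Dusp1, a phosphatase that ends MAP kinase signalling, by 4.48. The growth factor Hbegf rose by 4.86, the cornified envelope gene Sprr1a by 28.2-fold, and Klf2 by 5.06. Lars2 (6.47) and AY036118 (5.61) also rose, and both are uncertain because they resemble ribosomal RNA sequence and the counting of shared reads is not stated. AY036118 stood at 78.0 CPM in the CD326-negative library, against 5.35 and 3.32 CPM in the unsorted ones.

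The secretory product Spink1, a trypsin inhibitor of seminal fluid, fell in lobar luminal-like cells by 6.34-fold, from 96682 and 72714 CPM to 16333 CPM (adjusted p = 0.0136 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its level is uncertain, because fibroblast-like cells, which should lack it, held 13650 and 52202 CPM in the same libraries against 498 CPM with collagenase. Sbp, another secretory product, stood at 26706 and 27071 CPM in lobar luminal-like cells and at 34565 CPM with collagenase. The small nucleolar host RNAs Snhg9, Snhg6 and Snhg18 changed by -3.34, -2.66 and -2.23 on the log2 scale. The mitochondrial assembly and import genes Cox17 and Tomm6 changed by -2.43 and -2.37, and Usp50, Rab26os, Abhd2, Adam9 and Dcaf12l1 by between -2.87 and -2.16. Spinkl, a member of the Spink family, changed by -9.11, a value decided by cold protease library 2, which had 289 CPM beside 5.39 CPM in library 1 and 0.306 CPM with collagenase. Across 14711 genes tested, 754 rose and 638 fell. The largest cluster of the class was cluster 7 in cold protease library 1 (48.5%), cluster 0 in library 2 (48.0%) and cluster 8 in the collagenase library (62.8%). These clusters share the leading genes Ren1, C1s2 and C1rb, and no batch correction was applied. Whether they are a single lobar type split by library or different cells was not tested. With all 3 cold protease libraries as the reference, 40 genes passed, and with library 1 and the CD326-negative library as the reference, 31.

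In basal-like cells immediate early genes rose, and Trp63 and 5 of 12 cell cycle genes fell (7 adjusted over the list alone). Basal cells of the prostate depend on Trp63, a p53-family factor, and it fell by 4.07 (SE 0.88), from 207 and 289 CPM to 15.4 CPM (adjusted p = 0.00037 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Fosb stood at 631 CPM with collagenase and had 3 counts in all without it, a ratio of 2257 (95% counting interval 772 to 10950). Atf3 rose by 8.94 (SE 0.80), Fos by 8.01 (SE 0.81), Jun by 51.1-fold and Hbegf by 5.79. The AP-1 gene Fosl1 had 2 counts in the unsorted cold protease libraries, a ratio of 269 (74.1 to 2223). Egr3 rose by 6.32, Nr4a3 by 66.0-fold, Arc by 5.93, Dusp5 by 5.55, Csrnp1 by 5.52 and Lars2 by 5.84. Among genes that fell were the clock-related repressor Bhlhe41 (-5.38), Mia (-4.95), the protease inhibitor Spink5 (-4.38), Spon2 (-4.35), the glucocorticoid target Tsc22d3 (17.2-fold), Phlda3 (-3.99), Padi1 (-3.94), the glucose sensor Txnip (-3.31) and Spry2 (-3.25). Spinkl and Sva had 0 counts with collagenase and were at least 1897-fold and 376-fold lower; cold protease library 2 decides both, with 650 and 129 CPM beside 4.72 and 0.249 CPM in library 1.

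Of 13047 genes tested in basal-like cells, 439 rose and 381 fell. The class lay in cluster 1 in cold protease library 1 (73.6%), cluster 4 in library 2 (97.8%) and cluster 22 in the collagenase library (97.5%). These clusters share the leading genes Krt14, Krt15 and Lgals7, and no batch correction was applied. Whether they are a single type split by library or different cells was not tested. Median depths of basal-like cells in these libraries were 2994.5, 1999 and 10395 UMIs, and their Epcam stood at 166, 114 and 659 CPM. A change within the same cells, as for Trp63, therefore cannot be told apart from a difference in the cells compared. Of the secretory pathway list 5 of 12 genes rose (7 adjusted over the list alone), among them Agr2 by 3.03, Hspa5 by 2.94 and Hsp90b1 by 2.38. Of the cell cycle list 5 of 12 genes fell (7 adjusted over the list alone), among them Cenpf (-5.51) and Mki67 (-3.64). As lists these passed with camera at the preset correlation (adjusted p = 0.000309 and 0.000439), and had adjusted p = 0.927 with an estimated correlation and 0.653 and 0.527 with fry. Cluster 41, led by cell cycle genes, held 2 and 58 basal-like cells of cold protease libraries 1 and 2 and none of the collagenase library. Cenpf stood at 3.98, 15.2 and 0.215 CPM in these libraries and Mki67 at 7.46, 9.84 and 0.718 CPM. In this fit edgeR set the prior degrees of freedom to infinity, so the variance came from the trend over all genes although the design leaves 1 residual degree. The count of 820 became 129 with the stricter cell filter and 5886 with library 1 and the CD326-negative library as the reference.

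Fibroblast-like cells of the collagenase library combined immediate early genes with cytokines. Fosb stood at 1315 CPM against 7.81 and 1.31 CPM, a log2 fold change of 8.33 (SE 1.201, adjusted p = 6.54e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Atf3 rose by 8.06 (SE 1.16). The cytokine Il6 had 0 counts in both unsorted cold protease libraries and was at least 45.5-fold higher, and the chemokine Cxcl1, with 2 counts there, had a ratio of 259 (71.7 to 2142). Cxcl10 rose by 7.59 and the aggrecanase Adamts4 by 7.67. The hyaluronan synthase Has1 had a ratio of 460 (82.5 to 18200). Also among the genes with the largest change were Nefl at least 79.7-fold, Pcsk1n at least 72.8-fold and Nefm at least 41.5-fold, Sncg with a ratio of 306 (54.8 to 12110) and Tubb3 with one of 208 (37.2 to 8225). Pcsk1n changed sign under the stricter cell filter, to -1.26. Whether these transcripts came from most cells of the class, from a part of it or from other cells was not tested.

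In the lower direction only Spinkl and Snhg9 met every condition of the naming rule in fibroblast-like cells, so genes are given by size. Spinkl had 1 count with collagenase, a ratio of 2557 (458 to 101100), and cold protease library 2 decides it with 513 CPM beside 12.5 CPM. Snhg9 had a log2 fold change of -4.13 (adjusted p = 0.0347), Cox17 -3.18 (0.279), Oit1 -3.13 (0.204), Snhg20 -3.08 (0.212), Slc12a2 -3.01 (0.345), Cd52 -2.65 (0.363), Phpt1 -2.55 (0.384) and Snhg6 -2.51 (0.374), with adjusted p-values of edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment in brackets. Usp50 was 8.97-fold lower (0.133). Oit1 and Slc12a2 are leading genes of lobar luminal-like clusters 20 and 3, so RNA from other cells is not excluded as their source. Of 12065 genes tested 109 rose and 28 fell, with most of the class in cluster 10 in cold protease libraries 1 and 2 (78.2% and 50.9%) and in clusters 21 and 34 in the collagenase library (62.5% and 24.3%). The count became 0 with DESeq2 size factors, with each library clustered alone, without the secretory marker genes and without edgeR's legacy option, while the DESeq2 Wald test gave 81 higher and 19 lower. The prior degrees of freedom were 62.8 in the fit reported and 3.11 with DESeq2 size factors, and 759 genes had an unadjusted p under 0.05.

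Secretory transcripts in fibroblast-like cells differed between the libraries. Spink1, which fibroblasts should lack, stood at 13650, 52202, 53511 and 498 CPM in fibroblast-like cells of cold protease libraries 1 and 2, the CD326-negative and the collagenase library. At 1000 UMIs per cell, 100%, 100%, 99.9% and 25.03% of those cells had a Spink1 UMI. Secretory marker genes took 2.45%, 9.79%, 9.89% and 0.586% of the UMIs of fibroblast-like cells, and 15.5%, 12.8%, 33.2% and 8.25% in lobar luminal-like cells.

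Smooth muscle-like cells, few in number, had 11 of 20 measured immediate early genes higher in the collagenase library (18 adjusted over the list alone). The class held 31, 22, 123 and 24 cells in cold protease libraries 1 and 2, the CD326-negative and the collagenase library, all of them in cluster 36. Several genes had 0 counts in both unsorted cold protease libraries and are given as lower bounds. Atf3 was at least 114-fold higher, Fosb 41.6-fold, Lars2 31.1-fold, Maff 21.4-fold, Tnnc2 17.7-fold, the cytokine inhibitor Socs3 14.3-fold, Csrnp1 10.4-fold, Hbegf 10.2-fold, and Adamts4 and Col12a1 9.85-fold. Igfbp2, with 1 count there, had a ratio of 516 (92.3 to 20380). In the other direction Osr1, a transcription factor of urogenital mesenchyme, was at least 81.2-fold lower, Tspan8 52.4-fold, Apoc1 23.6-fold, Mia 15.1-fold, Pi15 13.1-fold, Fxyd3 12.4-fold and Oaf 10.5-fold. Osr1 is decided by cold protease library 1, with 1311 CPM beside 27.7 CPM in library 2. Cldn8 had a ratio of 51.0 (8.39 to 2093) and Defb50 a log2 fold change of -5.30. Defb50 is a leading gene of lobar luminal-like cluster 11, and secretory marker genes took 2.22% and 6.43% of the UMIs of smooth muscle-like cells in cold protease libraries 1 and 2 against 0.132% with collagenase, so RNA from other cells is not excluded as its source. Of 4499 genes tested 62 rose and 33 fell, with 443 at an unadjusted p under 0.05. The prior degrees of freedom were infinite here too. The DESeq2 Wald test gave 17 and 10, and the count became 0 with doublets kept, where the prior degrees of freedom were 4.505, and without edgeR's legacy option.

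Counted gene by gene, most immediate early genes rose in all 4 classes. In lobar luminal-like cells 20 of 21 measured genes passed (20 adjusted over the list alone), with a median log2 fold change of 3.69, and Myc did not pass (0.23). In basal-like cells 19 of 21 rose (20 adjusted over the list alone, median 3.52), in fibroblast-like cells 13 of 21 (19 adjusted over the list alone, median 4.16), and in smooth muscle-like cells 11 of 20 (18 adjusted over the list alone). With camera at the preset correlation the adjusted p was 3.71e-19 in lobar luminal-like and 7.6e-21 in fibroblast-like cells, and adjusted p = 0.927 with an estimated correlation. With fry the adjusted p was 0.113 in lobar luminal-like, 0.317 in basal-like, 0.403 in fibroblast-like and 0.205 in smooth muscle-like cells, so the list did not pass in any of them. Whether the response differs between classes was not tested.

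**Figure D2:**
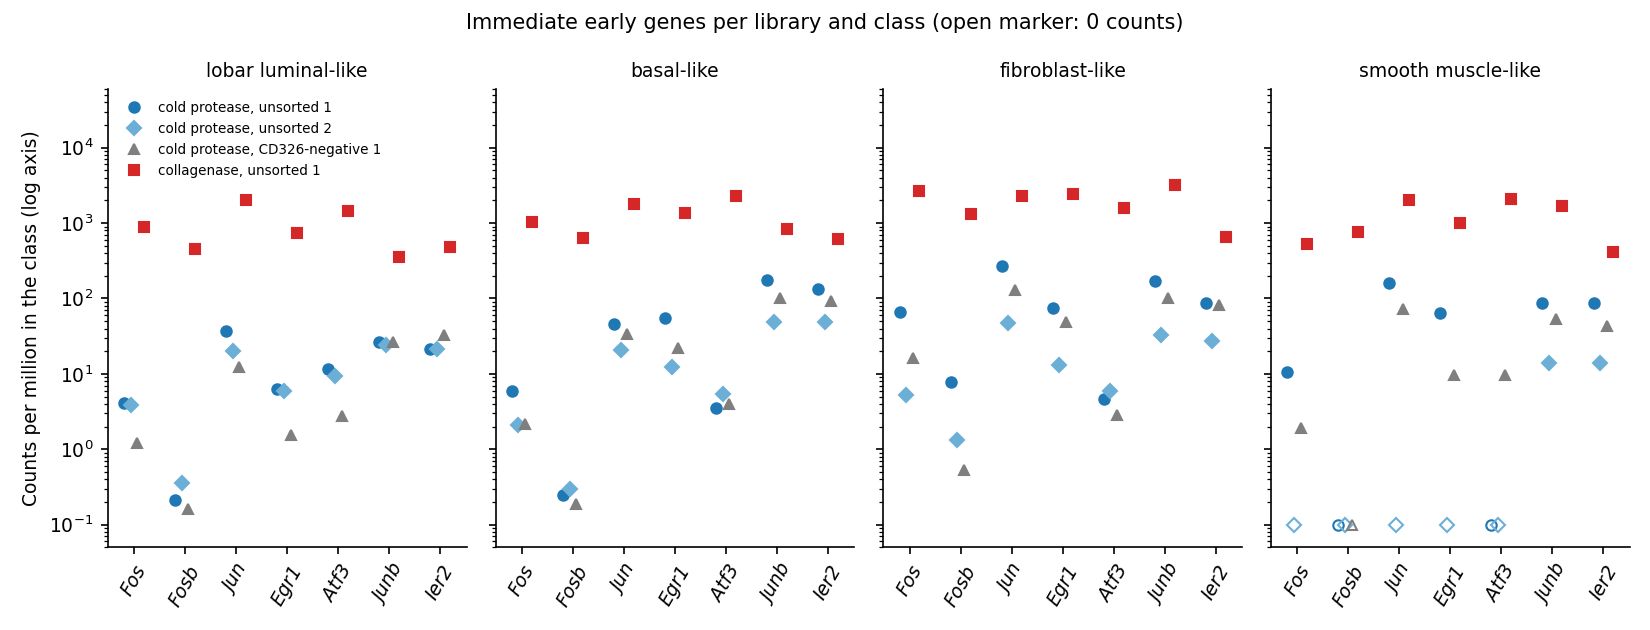
CPM (log axis) of 7 immediate early genes in 4 classes, with 1 point per library and open markers for 0 counts. In every panel the collagenase library lies above all 3 cold protease libraries, as for Fosb in lobar luminal-like cells with 452 CPM against 0.353 CPM or less.

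Inflammatory and stress lists followed the same direction in part. Of the NF-kB and chemokine list 7 of 12 genes rose in lobar luminal-like cells (9 adjusted over the list alone), led by Il1b with 5.22, Ccl7 with 4.97 and Ccl2 with 4.71. In basal-like cells 7 of 11 rose (8 adjusted over the list alone), in fibroblast-like cells 7 of 10 (9 adjusted over the list alone), with Cxcl2 at 10.06, and in smooth muscle-like cells 1 of 3, Csf1 (2 adjusted over the list alone). For Il1b, Ccl7 and Ccl2 in lobar luminal-like cells, RNA from other cells is not excluded as the source. Fibroblast-like and macrophage-like cells were 16.9% and 8.73% of the collagenase library, and doublets largely remain. Of the heat shock list 6 of 12 rose in lobar luminal-like cells (9 adjusted over the list alone), with Hspb1 at 2.24 and Dnajb1 at 1.83. Hspa1a rose by 2.15 and is uncertain, since its reads overlap those of the near-identical Hspa1b. Of that list 4 of 12 rose in basal-like cells (6 adjusted over the list alone) and 1 in fibroblast-like cells (3 adjusted over the list alone), with Dnajb1 at 3.55 and 3.49, and 0 of 12 in smooth muscle-like cells (4 adjusted over the list alone). The cold-inducible genes did not pass in any enzyme contrast: Cirbp stood at 0.63 and Rbm3 near 0 in lobar luminal-like cells. Mitochondrial transcripts, Malat1 and Neat1, taken as an RNA quality list, had 0 of 10 genes passing in each enzyme contrast. These differences between classes were not tested.

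The remaining lists held few changed genes. The matrix gene Thbs1, which also acts early after stress, rose in lobar luminal-like (3.54), basal-like (4.18), fibroblast-like (5.76) and smooth muscle-like cells (5.95). In lobar luminal-like cells the mucosal defence gene Pigr, which carries antibodies across the epithelium, fell by 1.55. Of the androgen response list 2 of 21 genes rose there and 1 fell (3 and 3 adjusted over the list alone): Acsl3 by 1.19, Zbtb16 by 1.18 and Aldh1a3 by -2.16. In smooth muscle-like cells the secreted Wnt regulators Sfrp1, Wif1 and Rspo3 rose by 5.27, 5.02 and 4.27. Wif1 is a leading gene of fibroblast-like clusters 24, 30 and 34, and Sfrp1 and Rspo3 were higher in fibroblast-like subcluster 1. Fibroblast-like cells were 16.9% of the collagenase library and 5.05% and 2.30% of the unsorted cold protease libraries. RNA from them is thus not excluded as the source of these 3 transcripts. The complement gene Cfd, factor D, fell in fibroblast-like cells by 9.30. It is named as a list member that passed, and it did not meet every condition of the naming rule.

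In the sort contrast few genes could be called in the stromal classes. In simulated counts it recovered 6.32% of 8-fold changes in fibroblast-like and 0.885% in smooth muscle-like cells, and none of the 2-fold ones, so a gene that did not pass may still differ. In fibroblast-like cells 1 of 12065 genes passed, Sva, lower in the CD326-negative library, and 157 had an unadjusted p under 0.05. The count was 13 with doublets kept and 21 with high doublet scores removed. In smooth muscle-like cells 1 of 4499 passed, Svs6, also lower, and 57 had an unadjusted p under 0.05. The DESeq2 Wald test called 0 genes in each. Both are seminal vesicle secretion genes, named here after their values were seen, and cold protease library 2 decides both: Sva had 81.3 CPM there and 0 in library 1, and Svs6 had 776 and 10.7 CPM. By size alone, fibroblast-like cells had Hba-a2 at a log2 fold change of 4.56 (adjusted p = 0.0814 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), AY036118 at 4.26, Retnla at 2.97, Apoe at 2.24 and Pdlim3 at 2.04. Spinkl stood at -5.75, Atf5 at -1.54 and Col4a1 at -1.30. In smooth muscle-like cells Rergl was at least 5.76-fold higher, Cryab had a ratio of 23.1 (6.27 to 192), Cxcl14 stood at 3.78 and Mt3 at -4.24, none of which passed. Of each list tested 0 genes passed in either class, with 1 lower complement gene in fibroblast-like cells, Cfd (-3.99), when adjusted over the list alone. The cell cycle list could not be tested in smooth muscle-like cells, and the secretory pathway list in smooth muscle-like cells had a median of -1.32 (camera adjusted p = 0.0005, and adjusted p = 0.927 with an estimated correlation). The contractile list there had a median of 1.11 (camera adjusted p = 0.00265, and adjusted p = 0.927 with an estimated correlation). With fry the adjusted p was 0.906 and 0.823 for these lists. Fry passed 2 other lists there that camera did not: heat shock (0.0311, camera 0.816), with a median of -0.0926, and NF-kB and chemokine (1.49e-14, camera 0.688). The latter has 3 measured genes, of which Cxcl1 and Cxcl10 had a log2 fold change of 0 with an SE of 0, so its p is not used.

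Proximal luminal-like cells were set against lobar luminal-like cells within each library, to ask how these luminal types differ beyond the markers that name them. The proximal cells carried mucosal defence and progenitor-associated genes, while the lobar cells carried more of the machinery for protein secretion. Ltf, the iron-binding antimicrobial lactoferrin, was higher by 8.15 (SE 1.12), at 231 against 0.174 CPM on average. Ly6a (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031, mm10), the stem cell surface marker Sca-1, was higher by 5.87 (SE 0.41), at 1014 against 10.2 CPM (adjusted p = 3.86e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The mucin Muc4 was higher by 5.95, Anxa3 by 5.59, the Wnt modulator Dkk3 by 5.30, Bmp2 by 4.72, the mucosal chemokine Cxcl17 by 4.62, Ly6c1 by 4.60, the peroxidase Gpx2 by 4.53, Thbs1 by 4.48, the survival gene Bcl2 by 4.30 and Wnt4 by 4.07. Ly6a and Ly6c1 belong to a family of similar genes, so reads may be split between them. Outside the lists the largest differences were Slc25a48 (181-fold), the homeobox gene Barx2 (6.79), the growth factor receptor Fgfr3 (6.34), Mecom (6.28) and Paqr6 (6.22). All of these pointed the same way in each of the 4 libraries.

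Lower in proximal luminal-like cells were Pcp4 (-4.13), Sdf2l1 (-2.46), Col6a3 (-2.34), the Wnt feedback gene Nkd1 (-2.28), the secreted growth factor Egf (-2.21), Bmp7 (-2.16), Agr2 (-2.13), the chaperone Hspa5 (-2.03), Pdia6 (-1.87), and Ube2c and Top2a of the cell cycle (-1.98 and -1.94). Manf, an endoplasmic reticulum stress factor, was 4.49-fold lower. Rnase1 (-3.06), Mt2 (-2.81), Fkbp11 (-2.77), Glb1l3 and C1s2 (each -2.71) were the largest outside the lists. All 12 genes of the secretory pathway list were lower (12 adjusted over the list alone), and 6 of 10 progenitor-associated genes were higher (6 adjusted over the list alone), among them Sox2 (3.77), Cd44 (3.42) and Sox9 (1.67). Of the mucosal defence list 6 of 9 were higher (6 adjusted over the list alone). The adjusted p by camera was 5.24e-06, 0.0021 and 0.00361 for these lists at the preset correlation, and adjusted p = 0.927 with an estimated correlation for each. With fry it was 0.0414, 0.00295 and 0.0695. The androgen response list was mixed, with 7 of 21 higher and 6 lower (7 and 6 adjusted over the list alone): Pmepa1 at 3.94, Aldh1a3 at 2.29 and Sord at -1.86. Among the steroid hormone genes the oestrogen receptor Esr1 was lower, at -1.52. Across 12095 genes, 2049 were higher and 2133 lower in proximal luminal-like cells.

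Basal-like cells were set against lobar luminal-like cells in the same way. They had more RNA of most contractile genes and less of every secretory pathway gene listed. Lcn2, an iron-scavenging defence protein, was higher by 5.08 (SE 0.43), at 206 against 4.19 CPM (adjusted p = 0.000302 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Ndrg1 was higher by 5.04, Steap4 by 4.96, the adhesion molecule Icam1 by 4.72, Tpm2 by 4.63, the activin subunit Inhba by 4.60, Wnt6 by 4.57, Bmp4 by 4.56, the basement membrane collagen Col4a2 by 4.29, Smtn by 4.05 and Ly6a by 4.01. Srd5a1, which makes dihydrotestosterone, was higher by 18.4-fold. The largest outside the lists were the atypical chemokine receptor Ackr4 (6.04), Dlk2 (5.47), the tight junction gene Cldn1 (5.41), Slco4a1 (4.93) and Mgst1 (4.84). All pointed the same way in each of the 4 libraries.

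The antibody transporter Pigr (-3.28), Egf (-3.07), Pcp4 (-2.82), Cxcl17 (-2.64), the peptidase Dpp4 (-2.60), Col6a3 (-2.52), Ceacam1 (-2.47), the mineralocorticoid receptor Nr3c2 (-2.46), Agr2 (-2.24) and Sdf2l1 (-2.17) were lower in basal-like cells. The oestrogen receptor Esr2 and the stem cell marker Prom1 were 6.52-fold and 4.81-fold lower. Abo (-3.92), Lrrc26 (-3.63), Oit1 (-3.45), Myo5c (-3.32) and Bmpr1b (-3.28) led the genes outside the lists. All 12 secretory pathway genes were lower again (12 adjusted over the list alone). Of the contractile list 7 of 10 were higher and 2 lower (7 and 2 adjusted over the list alone), with Flna at 3.71, Cald1 at 3.37 and Myl9 at 3.36. Of the growth factor list 5 of 8 were higher and 2 lower (5 and 2 adjusted over the list alone), with Pdgfa at 3.76 and Hgf at 3.57, of the Wnt list 5 of 12 were higher (5 adjusted over the list alone), with Wnt10a at 3.17 and Dkk3 at 3.13, and of the BMP and TGF-beta list 4 of 8 were higher and 1 lower (4 and 1 adjusted over the list alone). The androgen response genes Spdef and Tmprss2 were lower, at -2.16 and -2.15. Across 12804 genes 1922 were higher and 1989 lower. The count of 3911 was 1656 without cold protease library 1, 1158 without library 2 and 1012 without the CD326-negative library.

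**Figure D3:**
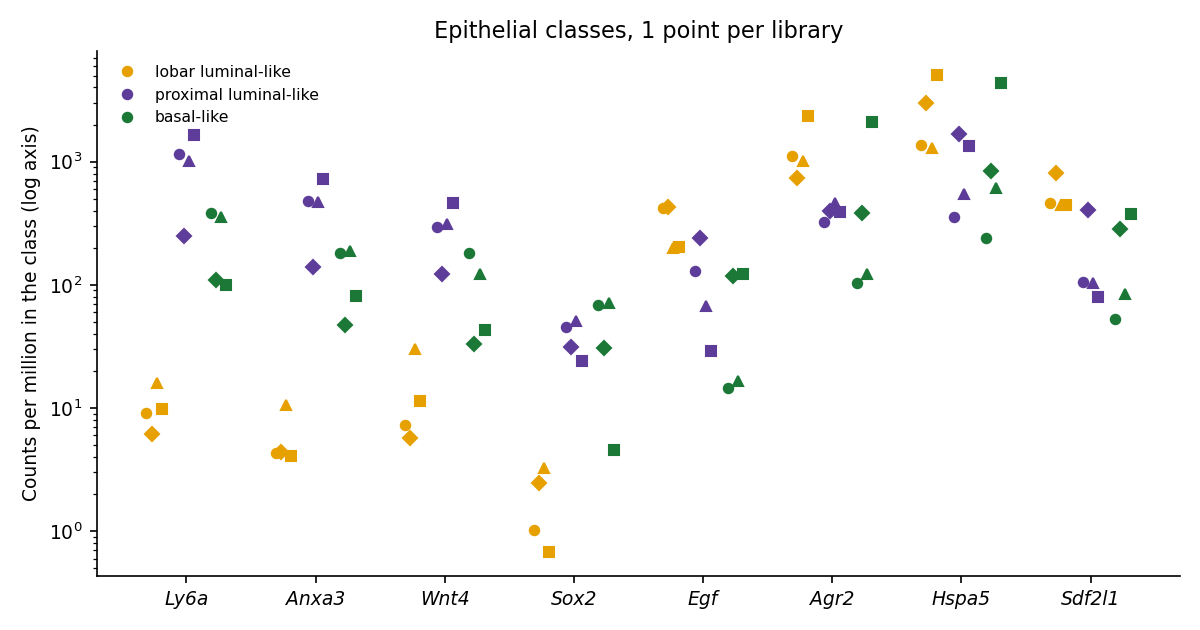
CPM (log axis) of 8 genes in lobar luminal-like, proximal luminal-like and basal-like cells, with 1 point per library (circle and diamond for cold protease libraries 1 and 2, triangle for CD326-negative, square for collagenase). Ly6a averages 1014 CPM in proximal luminal-like and 10.2 CPM in lobar luminal-like cells.

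Fibroblast-like cells were set against smooth muscle-like cells to describe the stroma. Fibroblast-like cells had more RNA of complement genes, and smooth muscle-like cells of contractile genes. Sult1e1, which inactivates oestrogens by sulfation (ENSMUSG00000029272, chromosome 5, 87575969 to 87591594, mm10), was higher by 8.09 (SE 0.42), at 1536 against 5.97 CPM (adjusted p = 5.24e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The complement genes C3 and C4b were higher by 6.04 and 4.13, Igf1 by 36.1-fold, Cd55, which shields cells from complement, by 4.65, Ly6c1 by 3.70, Fbln1 by 8.25-fold, Icam1 by 2.93, Ly6a by 2.67, Fbn1 by 2.55 and Fn1 by 2.42. Outside the lists Rnase4 (6.84-fold), Mpp6 (2.37), Pnp (2.11), Ablim1 and Vat1 (each 1.77) were higher. Myl9, the myosin light chain of smooth muscle, was lower in fibroblast-like cells by -6.37 (SE 0.36), at 25.7 against 2271 CPM. Tpm2 (-5.19), Mylk (-4.49), Pcp4 (-3.84), Flna (-3.06), Cald1 (-2.67), Smtn (-2.54) and Tgfb3 (-2.19) were lower too, as were Tpm1 (13.2-fold) and Pdgfa (3.47-fold). Outside the lists Sh3bgr (-5.18), Hspb2 (-4.63), Nexn (-4.44), Tinagl1 (-3.92) and Pgm5 (-3.74) were lower.

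Of the complement list 5 of 7 genes were higher in fibroblast-like cells (6 adjusted over the list alone), of the matrix list 5 of 18 (11 adjusted over the list alone, with 1 lower), and of the adventitial fibroblast list 2 of 7 (5 adjusted over the list alone). Of the contractile list 8 of 10 were lower (10 adjusted over the list alone). The adjusted p by camera for the contractile list was 2.09e-17 at the preset correlation, and adjusted p = 0.927 with an estimated correlation. With fry it was 0.0663. Of the growth factor list 2 of 7 were higher and 1 lower (2 and 1 adjusted over the list alone), with Fgf10, a growth factor for epithelial buds, higher by 2.27, and of the steroid hormone list 1 of 4 was higher (1 adjusted over the list alone). Gdf10 was higher by 2.11. Of 5947 genes tested 104 were higher and 76 lower. The total of 180 was 45 without the CD326-negative library, 116 without cold protease library 2 and 280 without the collagenase library.

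Fibroblast-like cells themselves fell into subclusters with different signalling genes, described here by list genes kept out of the clustering. The genes named were picked for the size of their change after their values were seen. Subcluster 0 (597 cells) was marked by Sult1e1, higher by 2.67 (SE 0.22) than in the other fibroblast-like cells, with Srd5a1 (2.55), C4b (2.29) and Igf1 (2.25), and by low Wnt2 (-6.75) and Sfrp2 (-3.97). Subcluster 1 (456 cells) had the BMP antagonist Chrdl1 (3.01), Inhba (2.39) and Col6a3 (2.36). Like subcluster 0 it had low Wnt2 (-3.88) and Sfrp2 (-3.81), and higher Sult1e1 (0.942). Subcluster 2 (456 cells) had the Wnt ligands Wnt10a (5.32), Wnt2 (4.23) and Wnt6 (4.07) with the Wnt antagonist Wif1 (3.92), and low Sult1e1 (-7.22). Subcluster 3 (327 cells) had the adventitial genes Cd55 (3.03), Dpp4 (2.88) and Pi16 (2233 against 245 CPM) with Col14a1 (3.22). Each of these values had the same direction in all 4 libraries. Subcluster 4 (281 cells, tested in 3 libraries) had the stem cell receptor Lgr5 (4.14), the elastic fibre genes Eln (3.38) and Mfap4 (427 against 47.8 CPM), and low Ccl2 (-4.89). Subclusters 5, 7 and 8, tested in 2 libraries each, carried epithelial genes: Spdef, Tmprss2 and Agr2 at 2.21, 1.79 and 1.63 in subcluster 5, Pigr at 4.08 in subcluster 7, and Agr2 at 3.70 in subcluster 8. Subcluster 6 carried the basal genes Pdgfa (3.48) and Lcn2 (3.15). Subcluster 9 held 50 cells, all from the collagenase library, and was not tested. In all, 155 list genes passed in at least 1 of the 9 subclusters tested. The subclusters were found in the same cells, and list genes may vary together with the genes that formed them. The p-values thus describe the subclusters and are too small as evidence that separate ones exist.

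**Figure D4:**
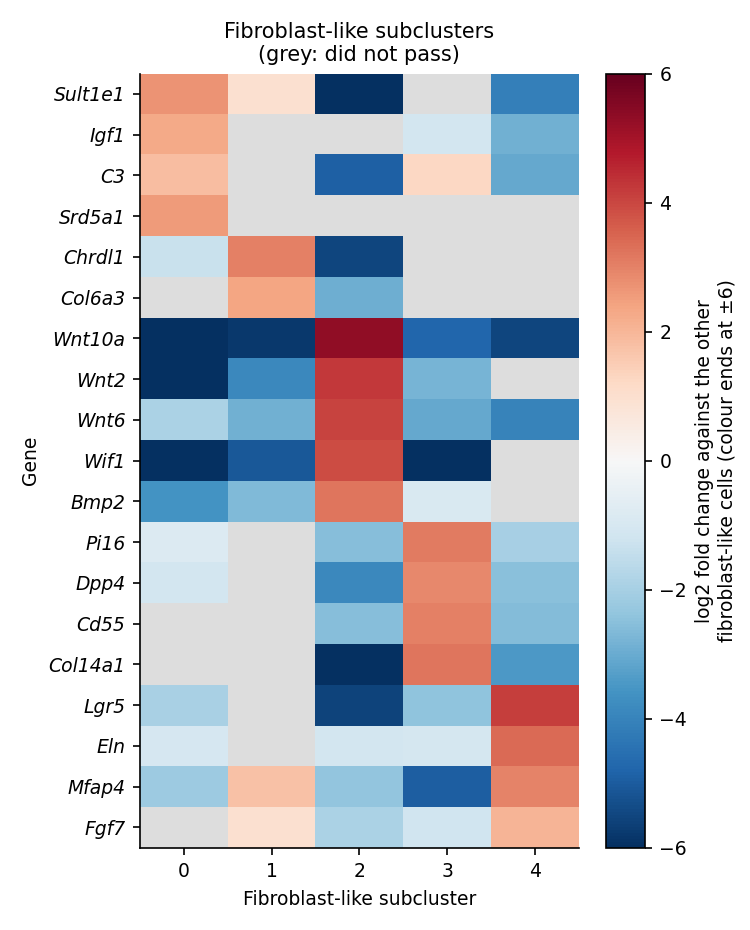
Log2 fold change of 19 list genes in fibroblast-like subclusters 0 to 4 against the other fibroblast-like cells, as colour from -6 to 6, with grey for genes that did not pass. Wnt10a reaches 5.32 in subcluster 2 and Lgr5 4.14 in subcluster 4.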

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

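The tests on kit, collagenase digestion, Epcam depletion and free RNA in basal-like and in lobar luminal-like cells, with their bounds, were chosen after the result was seen, and the tests on secretory share and on free RNA in all epithelial class names before.

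Cells outside every named class formed 4 clusters without high doublet scores, a signal in cells that no planned comparison used; cluster 18 entered only an added ratio for macrophage-like cells. Cluster 15 (848 cells) was led by Svs2, Cdo1, Pate4 and Pfkfb3 and made up 4.19% and 2.36% of cold protease libraries 1 and 2, 0.634% of the CD326-negative and 0.0199% of the collagenase library. Cluster 18 (672 cells), led by the myeloid genes Retnla, Lyz1, Ccr2 and Cd209a, was 2.14%, 0.926%, 2.42% and 0.318%. Cluster 31 (259 cells) was led by Atp6v1g3, Clcn5 and Foxi1, genes of proton-pumping ionocyte cells, and was 1.95%, 0.599%, 0.146% and 0.0199%. Cluster 39 (111 cells), led by Clec9a, Wdfy4 and Il12b of cross-presenting dendritic cells, was 0.157%, 0.125%, 0.240% and 0.816%.

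Immediate early genes were higher in every tested class of the collagenase library, and the technical and biological readings could not all be separated. Secretory transcripts taking up the cold protease counts are argued against as the cause: with those genes left out, the list's median log2 ratio of CPM in fibroblast-like cells was 4.08, beside 4.14 with them, and its median fold change in edgeR was 4.18 (median SE 0.919), beside 4.16 (0.984). No gene then passed in edgeR, against 137 before, because the prior degrees of freedom went from 62.8 to 3.75: Fosb was 8.35 (SE 1.197, adjusted p = 0.791 by the quasi-likelihood test with Benjamini-Hochberg adjustment), beside 8.33 (SE 1.201). A kit difference that acts on each gene alike in every class stays open, since the median over genes of the range across 3 classes was 1.98, just short of the bound of 2 set for excluding it, at a median SE of 0.686. Digestion with collagenase, the difference the design names, also stays open: the lowest median over the 4 classes was 3.52, but the kit, and any difference between mice, goes the same way.

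Epithelial cells remained the majority of the CD326-negative library. A depletion that left lobar or proximal luminal-like cells with little Epcam RNA is argued against for the class averages only. The lowest ratio of Epcam CPM to the higher unsorted library was 1.06 (1.1997 in proximal luminal-like cells). The clusters that made up these classes differed in share between the libraries, so lower Epcam RNA within a cluster is not excluded. For basal-like cells such a depletion stays open, as their Epcam was as low as 0.496 of the highest of 4 non-epithelial classes. RNA does not measure the surface protein, which cold protease digestion may have altered, and that was not tested. Non-epithelial cells named basal-like because of free RNA are argued against by the secretory transcripts. Their share in basal-like cells was 0.224 of the lowest among fibroblast-like, macrophage-like and endothelial-like cells. Cldn4 was at 8.05 times the highest of them, but it was picked with these values in view. Other epithelial genes lay closer. In basal-like and macrophage-like cells Krt18 was at 518 and 268 CPM, Krt8 at 327 and 87.8 CPM and Epcam at 198 and 125 CPM. Cdh1 was at 66.7 CPM in basal-like cells, beside 39.5 CPM in endothelial-like cells. The test set beforehand left free RNA undecided, at a lowest ratio of 2.36 between the bounds of 2 and 3, but markers of 6 other cell types, per cell and relative to those types, summed to 0.0696 in lobar luminal-like, 0.0849 in proximal luminal-like and 0.246 in basal-like cells, the last only just under a bound of 0.25 set with these values in view and almost all from Dcn (0.322 of its level in fibroblast-like cells, against at most 0.0204 for the other 7 fibroblast markers).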

How the results depend on the processing

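The reference of cold protease library 1 with CD326-negative, removal of the highest doublet scores, edgeR without its legacy option and other cluster sets for macrophage-like cells were chosen after seeing the data. The cause of each shift below was not tested, except that fewer libraries or cells enter some fits by construction.

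Genes called in the enzyme contrast of lobar luminal-like cells (1392) were 712 with the DESeq2 Wald test, 872 with the stricter cell filter, 852 at resolution 2, 832 with each library clustered alone, 40 against all cold protease libraries, 31 against library 1 with CD326-negative and 449 without the legacy option. In basal-like cells (820) they were 379 with DESeq2, 430 with doublets kept, 129 with the stricter and 405 with the looser cell filter, 468 at resolution 2, 191 with each library clustered alone, 5886 against library 1 with CD326-negative and 485 with high doublet scores removed. In fibroblast-like cells (137) they were 0 with DESeq2 size factors, 214 with doublets kept, 75 with the stricter filter, 0 with each library clustered alone, 0 without secretory genes, 1750 against library 1 with CD326-negative, 0 without the legacy option and 356 with high doublet scores removed. The prior degrees of freedom, estimated from 1 residual degree, were 62.8 in the fit reported and 3.11, 5.74, 3.75 and 6.23 in the fits with 0 calls. In smooth muscle-like cells (95) they were 27 with DESeq2, 0 with doublets kept, 189 against all cold protease libraries, 837 against library 1 with CD326-negative and 0 without the legacy option; the other cell filters, resolution 2 and score removal left too few cells for a value.

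In the sort contrast of fibroblast-like cells (1) the count was 0 with DESeq2 size factors, the DESeq2 Wald test, the stricter filter, each library clustered alone, secretory genes left out and no legacy option, 9 with no low-count filter, 13 with doublets kept, 8 with the looser filter, 8 at resolution 2 and 21 with high doublet scores removed. In smooth muscle-like cells (1) it was 0 with the DESeq2 Wald test, no low-count filter, doublets kept, secretory genes left out and no legacy option, and 5 with each library clustered alone.

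The class contrasts depended on the block and the libraries. Proximal against lobar (4182) gave 1698 without the library block and 1651 with cells thinned to 1000 UMIs. Basal against lobar (3911) gave 1592 without the block and 1012 to 5831 with 1 library left out. Fibroblast against muscle (180) gave 876 with no low-count filter, 428 with the looser filter, 337 at resolution 2, 55 without the block and 45 to 280 with 1 library left out. The 40 list calls of camera became 0 with an estimated correlation, and 7 of them also passed with fry, 1 of these in smooth muscle-like cells with 3 measured genes. The 0 calls decide little, because camera with an estimated correlation rests on 1 or 3 residual degrees of freedom here.

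The enzyme share ratio of lobar luminal-like cells (0.993) was 0.584 with the stricter filter, 0.664 at resolution 2, 0.744 with each library clustered alone and 0.695 with high doublet scores removed. The ratio of fibroblast-like cells (4.59) was 8.31 with the stricter filter and 3.34 to 7.33 against a single unsorted library. That of macrophage-like cells (2.33) was 1.54 without cluster 37 and 1.71 with unnamed cluster 18, and that of T/NK-like cells (2.55) was 9.51 with the stricter filter, or 1.74 to 4.80 against a single unsorted library. Smooth muscle-like cells (1.36) gave 6.53 with the looser filter, 5.37 at resolution 2, 5.73 with high doublet scores removed and 0.783 to 5.04 against a single unsorted library.

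Reversed were Pcsk1n in fibroblast-like cells with the stricter filter (-1.26), and the median of the immediate early list in the sort contrast without cold protease unsorted library 1 in fibroblast-like cells (1.12, and -0.62 without library 2) and without library 2 in smooth muscle-like cells (-0.0647, and 1.89 without library 1). Of other values for single genes, lists and class shares under the alternatives, 2966 stayed the same, 332 lost their call, 29 gained one and 284 without a test moved. Values with a test stayed the same when they kept direction and side of the threshold. Class shares did so when they lay within the interval of the main setting. Fold changes against a single unsorted library did so when they lay within the spread of the unsorted libraries. No paired analysis was possible because replicate numbers follow the order of deposit and the labels tie no libraries of different groups to a shared mouse, litter or day.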

Other observations

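The tests of both Spink1 readings were chosen after the result was seen, and the splits of the samples before.

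Secretory transcripts were found in cells of the other classes measured in cold protease library 2, and 2 sources were tested. Free RNA of 1 fixed composition as the whole source is argued against: the ratio of Spink1 to Svs5 counts was 11.4 in fibroblast-like, 12.4 in macrophage-like, 8.56 in endothelial-like and 5.55 in T/NK-like cells, and the highest was 2.23 times the lowest. Doublets with lobar luminal cells as the whole source are also argued against, since at 1000 UMIs per cell 100% of the cells in each of these classes had a Spink1 UMI. A mixture of sources was not tested.

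Other splits of the sums were fitted for the class contrasts. The sums are paired by library, and only 8 splits part every pair as the real split does, too few for a share under 0.05. Of these 8 splits 1, the real one, gave as many as the 4182 genes of proximal against lobar luminal-like cells, and the highest of the others gave 0. The same held for the 3911 genes of basal against lobar and the 180 of fibroblast against muscle. The classes were found in the same cells.

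Unnamed clusters 17 and 35 had high doublet scores. Cluster 17 (733 cells, 728 of them in cold protease library 2) was led by basal genes such as Trp63 and Krt5 and also carried lobar luminal markers, and cluster 35 (204 cells, 201 of them in the CD326-negative library) was led by Spink5, Kcnk3 and Spink1.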
